A study of Mus musculus with 46 samples.

How the data were processed

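RNA was measured by bulk sequencing in 46 libraries of sorted mouse microglia, spread over 4 deposited tables that share no library by their labels. The labels name bcl2fastq, HISAT 0.1.5, SAMtools, HOMER and DESeq2, in no stated order or role, with the genome build mm9, and they cite an oligo(dT) capture method. How genes were annotated, whether molecular identifiers were collapsed and how the values were scaled is not stated. In each deposited table the values are signal: read counts per gene that the authors multiplied by 1 factor per library. In every library the values were whole multiples of that factor. Of the 560156 values above 0, at least 99.95% per library lay within 0.1 read of a whole number once divided by it. The recovered totals, 898451 to 4573063 reads per library, are the depth behind each value. They limit the precision of genes with few reads, and they cover counting error only, since amplified reads need not be independent molecules. All 4 tables list 1 row per gene symbol and give no positions. Every column had a sample.

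The groups, comparisons, tests, gene lists, rule for named genes and first set of alternatives were fixed before the data were examined. The fixed design planned edgeR for tables of counts and limma for tables of normalized values. Because the tables held normalized values, limma 3.58.1 in R 4.3.3 gave every reported fold change, standard error and adjusted p. It was fitted to log2(value + 1) with a variance trend. Genes with a value of at least 1 in as many libraries as the smallest group of the comparison were tested. Each table had 1 fit with 1 mean per group, and the newborn comparison was fitted on its own 5 libraries. A gene counted as called when its Benjamini-Hochberg adjusted p was under 0.05. An interaction is the LPS effect in Dicer-deficient microglia minus that in control microglia, on the log2 scale. The p-values measure the spread between these libraries, since the labels do not state that each library came from a separate animal.

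In total, 28 gene lists were fixed in the same way. They cover microglial stages and identity, inflammatory and interferon responses, antigen presentation, cell division, genome maintenance, small-RNA biology, metabolism, ribosomes, lysosomes, genes induced by dissociation, markers of other cells and sex-linked genes. Each list was tested with camera against all other genes at a preset correlation of 0.01, and again with the correlation estimated from the data. The list p-values were adjusted over the 28 lists of a comparison. Beside each list test stands the number of its measured members that were called over all genes, and the number called when adjusted over the list alone. Some lists share members: Jun and Junb stand in both the adult-stage and the dissociation list, and several homeostatic genes are also adult-stage genes. Many markers of border macrophages and monocytes are expressed by microglia as well.

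Named genes follow 1 rule. Dicer1 comes first. Then come the 8 highest and 8 lowest fold changes among called genes whose groups did not overlap in any library and whose mean level was at or above the median of the tested genes. Last come up to 3 members of each list with the smallest p. Unnamed gene models were left out, only part of the genes that the rule gave are named, and 2 are not reported here. For an interaction the non-overlap condition was dropped, and where fewer than 5 genes were called in a direction, genes with the smallest p filled up to 5 as values. Genes named outside this rule are said to be chosen after their values were seen.

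Alternatives planned before the data were examined were a pseudocount of 0.1 or 5 in place of 1, no filter, a fit of only the groups compared, the replicate number as a block, an estimated correlation for the lists, and each library left out in turn. Chosen after seeing the data were edgeR 4.0.16 quasi-likelihood tests (TMM or RLE scaling) and DESeq2 1.42.0, both on the recovered reads. So were sex read from sex-linked genes as a covariate, and the LPS correlations without 1 library. A missing DESeq2 p was not told apart from a failed test. Refits without a library kept the full comparison's filter number, a change after a first run.

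The procedure was tested on simulated data built from these tables, in which 200 genes were raised or lowered by 2-fold or 4-fold. In the adult comparison limma called 35.4% of the tested genes changed 2-fold and 79.6% of those changed 4-fold. The shares were 24.2% and 70.8% in total brain after LPS, 2.06% and 45.2% for the total brain interaction, and 3.03% and 26.5% in the hippocampus after LPS. They were 47.5% and 83.8% for P0 against E14 and 8.08% and 71.4% in the newborn comparison. Between 0 and 7 unchanged genes were called per simulation with limma. DESeq2 called 25 unchanged genes among 74 calls in the hippocampus simulation. The set of raised genes was called at both correlations in every simulation, and 0 of 50 random sets were. Reads were recovered from the simulated values in every column. A check for duplicates compared all 60 pairs of libraries within a group. The chi-square per degree of freedom of their reads, near 1 where only counting differs, was 2.3 to 48.5.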

Results

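The data were normalized read counts in microglia, the resident macrophages of the brain, sorted from control or Dicer-deficient mice. Dicer1 encodes the endonuclease that cuts precursor microRNAs. The adult table held 4 control libraries, from mice that carried a tamoxifen-inducible Cre driven by Cx3cr1, and 3 Dicer-deficient libraries, all at steady state, with 898451 to 1991621 reads. In the total brain table were 3 steady-state controls, 4 controls taken 6 h after lipopolysaccharide (LPS, a bacterial cell wall component), 3 steady-state Dicer-deficient libraries and 4 Dicer-deficient libraries after LPS, with 2244169 to 4573063 reads. The labels of its steady-state libraries also say PBS, and whether those mice were injected is unclear. The hippocampus table had 2, 2, 3 and 2 libraries in the same order, with 1817611 to 4143142 reads. The developmental table had control libraries at embryonic day 14 (E14, n = 4), at birth (P0, n = 5) and in adults (n = 5), and 2 Dicer-deficient libraries at P0, with 992317 to 3460338 reads. Changes below are log2 fold changes ± SE from limma, levels are mean normalized read counts ± SD, and a gene or list is said to have risen or fallen only if it passed its test. Genes of a list were also called with p adjusted over the list alone; either way means by both adjustments. For lists, estimated marks the adjusted p with a correlation estimated from the data. Groups follow the sample labels, since the series text gives both adult genotypes the same string, and 3 rather than 4 Dicer-deficient total brain libraries after LPS.

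Dicer1 itself was not called in any of the 15 comparisons. In the adult table its level was 119 ± 24.1 in controls (n = 4) and 137 ± 18 in Dicer-deficient microglia (n = 3), and at steady state in total brain 120 ± 16.7 and 85.9 ± 18.8 (n = 3 each). Dicer1 transcripts can still be captured at their 3′ end after deletion of internal exons. If the libraries hold 3′ tags, as the method cited in the labels does, Dicer1 levels do not measure the deletion.

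The adult table asked how loss of Dicer alters microglia in the unchallenged adult brain (n = 3 Dicer-deficient, 4 control). Ifi30, a lysosomal thiol reductase of antigen processing, rose from 1180 ± 119 to 6250 ± 1280, and Nid2, a basement membrane protein, rose from 237 ± 47.6 to 1650 ± 318. Perp, a target of p53, rose from 34.2 ± 12.9 to 452 ± 324. The chemokine Ccl3 fell from 4130 ± 592 to 857 ± 288, and H2-Ob, a regulator of MHC class II loading, fell from 375 ± 77.8 to 73.9 ± 13.9. In all, 348 genes rose and 221 fell of 11045 tested, of which 158 and 157 changed at least 2-fold.

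Among the strongest adult increases, with adjusted p of at most 0.0145, were Nid2 (2.80 ± 0.20), the inhibitory receptor Siglec5 (2.80 ± 0.28), Psat1 of serine synthesis (2.79 ± 0.47), Upk1b (2.65 ± 0.30), Hsf2bp (2.56 ± 0.43), Fcrl1 (2.53 ± 0.57) and the histone gene Hist1h2be (2.43 ± 0.28). Fcrl1 lost its call without control 2 and with DESeq2. Among genes at or above the median level whose groups did not overlap, the strongest decreases, with adjusted p of at most 0.00182, were H2-Ob (-2.32 ± 0.26), Ccl3 (-2.31 ± 0.19), the TNF-family ligand Tnfsf12 (-2.28 ± 0.27), Tmsb10 (-2.25 ± 0.25), the B-cell receptor component Cd79b (-2.10 ± 0.35), Chst7 (-2.07 ± 0.31), Fblim1 (-1.98 ± 0.25) and Oaf (-1.86 ± 0.27). Reads of the histone genes can be shared between near-identical copies, so the value of a single histone gene is uncertain.

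Of 25 immediate early genes induced by tissue dissociation, 12 fell and none rose in adult Dicer-deficient microglia (15 fell and 3 rose over the list alone). They included Egr1 (-1.18 ± 0.18), Atf3 (-1.39 ± 0.23) and Junb (-1.03 ± 0.18), and the list fell with adjusted p = 5.43e-07; 0.499 estimated. The cytokine list fell, with 4 of 25 genes lower, among them Ccl4 (-1.70 ± 0.27) and Cxcl16 (-1.25 ± 0.25), and 5 lower and 1 higher over the list alone (adjusted p = 0.00124; 0.544 estimated). Of 17 adult-stage genes 3 fell, Jun by 0.85 ± 0.15, and 4 over the list alone (list adjusted p = 0.00877; 0.499 estimated). The type I interferon list fell with a median of -0.85, although 0 of its 38 genes were called either way (adjusted p = 3.48e-05; 0.547 estimated).

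Lists that did not pass in adults held called genes as well. In glycolysis (adjusted p = 0.188) Hk3 (-1.67 ± 0.22), Pfkfb3 (-1.0 ± 0.18) and Eno1 (-0.92 ± 0.19) were among 4 of 22 that fell, while 1 rose (4 and 2 over the list alone). In antigen presentation (adjusted p = 0.132) H2-DMa (-0.85 ± 0.16) and H2-D1 (-0.90 ± 0.18) were among 3 of 23 that fell (4, with 1 higher, over the list alone). The lysosomal protease gene Ctsl (1.23 ± 0.18) was among 3 of 32 lysosomal genes that rose (list adjusted p = 0.35), whereas Psap (-0.81 ± 0.16) and Ctsc (-0.72 ± 0.15) fell (5 and 5 over the list alone). In the small-RNA pathway (adjusted p = 0.192) 3 of 21 rose either way, among them the Argonaute partners Tnrc6b (0.83 ± 0.16) and Tnrc6a (1.03 ± 0.20). Of 28 let-7 targets, genes repressed by that microRNA family, only Myc was called (-1.47 ± 0.28); over the list alone, 7 were higher and 3 lower (median 0.27, adjusted p = 0.113). Numb, a target of miR-146a, rose (0.96 ± 0.16), and Sparc, a matrix protein, rose by 1.02 ± 0.20.

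In the adult comparison the homeostatic list had 1 of 30 genes higher and 1 lower (adjusted p = 0.247), the lower one Bin1 (-0.64 ± 0.15), whose call was lost without control 2, control 3 or Dicer-deficient 1, and with sex as a covariate. The median, mean and test of a list differed in sign for DNA replication, p53 response, lysosome and border macrophages, none of which passed. Of 5 lymphocyte markers Cd79b fell (list adjusted p = 0.247), and S100a8, a neutrophil gene, was 0 in all 7 libraries. Without control 3, control 4 or Dicer-deficient 1 the number of called genes was 344, 368 or 346, and 354 with sex as a covariate. Without Dicer-deficient 1, 178 rose and 168 fell, without control 1, 246 and 138, and with edgeR 52.9% (TMM) of the called genes were higher, against 61.2%. The p53 list (adjusted p = 0.933) had 2 of 26 genes higher and 1 lower, either way, the lower one Ephx1 (-1.31 ± 0.37), a call that of 7 refits only the one without Dicer-deficient 1 kept.

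**Figure D1:**
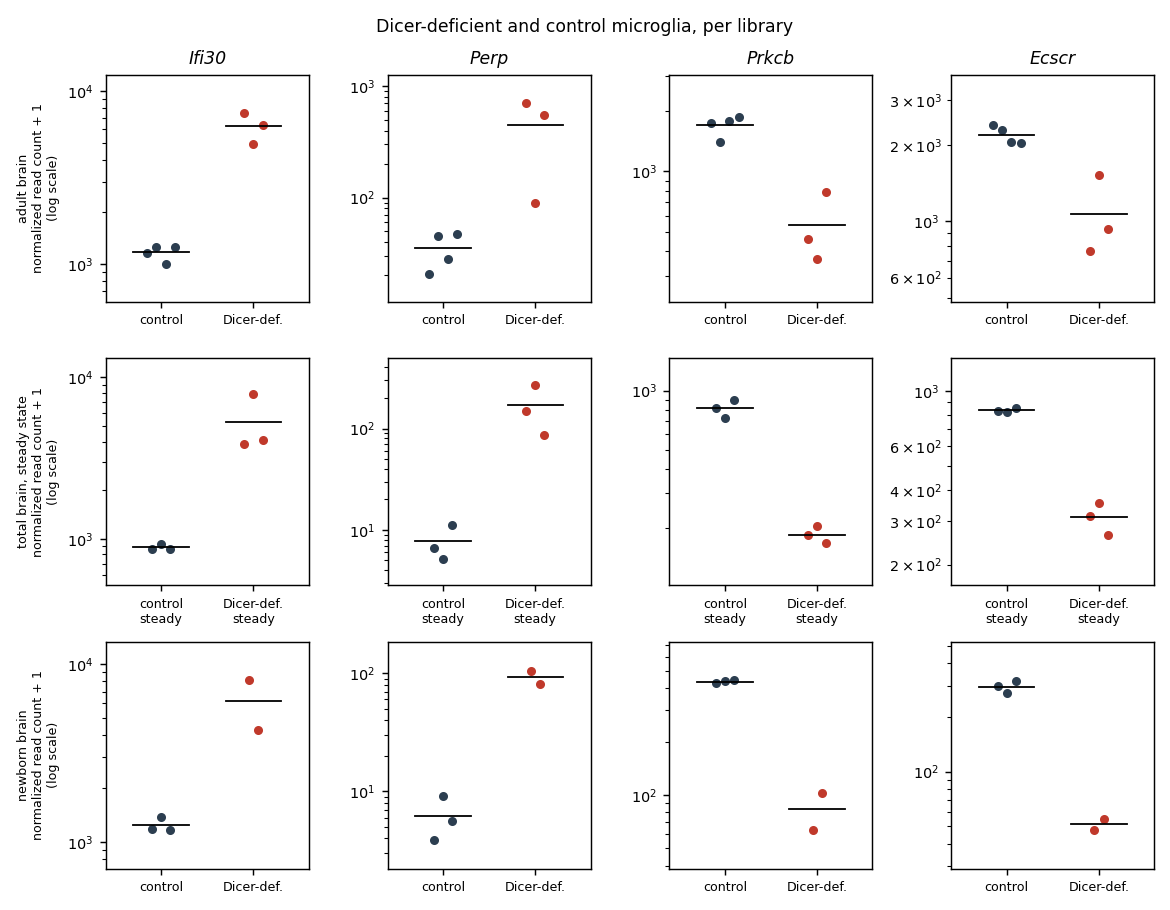
Normalized read count + 1 (log scale) of Ifi30, Perp, Prkcb and Ecscr in control and Dicer-deficient microglia of the adult, total brain steady-state and newborn comparisons. Points are libraries and lines are group means; Ifi30 and Perp lie higher and Prkcb and Ecscr lower in Dicer-deficient libraries in each comparison.

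In whole brain at steady state the same question was asked in separate libraries (n = 3 each). Chst2, a sulfotransferase, rose from 16.5 ± 8.32 to 246 ± 64.8, Ifi30 from 886 ± 39.1 to 5270 ± 2240, and Perp from 6.73 ± 3.18 to 168 ± 93.5. The lipoprotein gene Apoe fell from 2430 ± 704 to 623 ± 79.6, Prkcb, a protein kinase C, from 810 ± 85.5 to 184 ± 19.5, and the checkpoint receptor gene Lag3 from 578 ± 221 to 116 ± 27.2. Of 13423 genes tested, 107 rose and 185 fell, 87 and 169 of them at least 2-fold.

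Further increases in total brain were Siglecf (2.80 ± 0.44), Pde2a (2.62 ± 0.41), Igsf8 (2.54 ± 0.28), the potassium channel gene Kcnn4 (2.36 ± 0.37) and Nid2 (2.30 ± 0.38). Further decreases were Chst7 (-3.03 ± 0.30), Anxa5 (-2.54 ± 0.41), Ddah2 (-2.28 ± 0.42), Clec2d (-2.20 ± 0.36), Fam129b (-2.09 ± 0.33) and Oaf (-2.03 ± 0.29). Their adjusted p was at most 0.00648. Sox4 (-2.30 ± 0.49) and Ctsl (1.35 ± 0.29) lost their calls without control 7, control 9 or Dicer-deficient 11b, and Cd79b (-2.67 ± 0.54) without control 7, control 8 or Dicer-deficient 5.

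Ribosomal protein genes fell as a list in steady-state total brain, with a median of -0.48 and 1 of 46 genes called lower, or 10 over the list alone (adjusted p = 1.07e-05; 0.532 estimated). Immediate early genes fell, 4 of 26 lower and 8 over the list alone, with Egr1 at -1.90 ± 0.31 (adjusted p = 0.0111; 0.889 estimated). Adult-stage genes fell with 2 of 18 lower either way (adjusted p = 0.00703 and 0.652 estimated), among them Jun (-1.57 ± 0.35), which is also in the immediate early list. Perinatal genes fell with 4 of 24 lower and 1 higher, or 8 and 2 over the list alone (adjusted p = 0.0128; 0.318 estimated). Neuronal markers rose with 1 of 15 higher either way, Snap25, which was listed at 0 in all 3 controls and at 12.5 ± 5.05 in Dicer-deficient libraries (adjusted p = 0.00703; 0.318 estimated).

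The immediate early list call was lost in 2 of 6 refits, with adjusted p = 0.26 without control 9. The adult-stage call was lost without Dicer-deficient 11b (adjusted p = 0.116), in which Cx3cr1 was at 2490 against 5330 to 5580 in the other 2 Dicer-deficient libraries. The perinatal call was lost without Dicer-deficient 5 (adjusted p = 0.106). The number of called genes was 153, 127 and 89 without control 7, 8 and 9, and 143 without Dicer-deficient 5, and 61 genes rose and 136 fell without 11b. With edgeR and TMM scaling, 51.9% of the called genes were higher, against 36.6%. The p53 list had 1 of 27 genes higher (adjusted p = 0.477) and the let-7 list 0 of 27 (median 0.03, adjusted p = 0.393). Median, mean and test differed in sign for 10 lists that did not pass, namely antigen presentation, mitosis, p53, small RNA, miR-155 and miR-146a targets, oxidative phosphorylation, lysosome, lymphocytes, astrocytes and oligodendrocytes.

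The hippocampus gave fewer calls at steady state (n = 3 Dicer-deficient, 2 control), 19 higher and 2 lower of 12366. All 3 Dicer-deficient libraries held female Xist (622 to 693) and Y genes (242 to 298). Whether each is 1 mouse is unknown. Lcn2, an acute phase protein, rose from 63.7 ± 33.9 to 761 ± 189 (3.63 ± 0.40). Siglecf rose from 124 ± 80.9 to 1330 ± 51.8 (3.57 ± 0.39). Ifi30 rose by 2.37 ± 0.26, a call lost without control 2, and Ecscr fell by 1.74 ± 0.24, a call lost without control 1 or 2, or Dicer-deficient 4 or 5. Psat1 (3.61 ± 0.49) and Socs3 (1.79 ± 0.21) rose, calls lost without control 2 or Dicer-deficient 5 and, for Psat1, 6. Nid2 (2.86 ± 0.45) and Cst7 (2.42 ± 0.38) rose, calls lost without control 2 or any 1 Dicer-deficient library, and with a pseudocount of 0.1. Prkcb was at -1.36 ± 0.25 (adjusted p = 0.0589), Lag3 at -1.80 ± 0.32 (adjusted p = 0.0532), and Epb41l3 and Derl3 were listed at 0 in all Dicer-deficient libraries against 41.9 ± 10.6 and 20.9 ± 5.28 in controls.

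Markers of monocytes and neutrophils were higher in Dicer-deficient hippocampus, with a list median of 2.66 and 0 of 19 genes called either way (adjusted p = 3.4e-05; 0.558 estimated). S100a8 was 1530 to 2070 there and 104 and 498 in controls. Whether such cells gave the higher Lcn2 was not tested. Erythroid markers rose (median 2.49, 0 of 7 called either way, adjusted p = 0.0197; 0.558 estimated) and adult-stage genes fell (median -0.27, 0 of 18 called either way, adjusted p = 0.0497; 0.558 estimated). Both calls were lost without control 1 (adjusted p = 0.118 and 0.416), in which Cx3cr1 was at 688 against 7140 in control 2. The count was 12, 5, 9, 4 and 8 without control 1, control 2, and Dicer-deficient 4, 5 and 6. It was 8 and 42 with pseudocounts of 0.1 and 5, 43 with only the groups compared, 33 and 35 with edgeR and TMM or RLE scaling, and 231 with DESeq2. With these scalings 69.7% and 71.4% of called genes were higher, against 90.5%. Signs of median, mean and test differed for the mitosis, p53 and immediate early lists, which did not pass.

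Across the genes tested in both the adult and the total brain table, the steady-state Dicer effects had a Pearson r of 0.446 over 10674 genes, which are not independent replicates. Of 557 genes called in adults, 514 (92.3%) had the same sign in total brain. Called in both were 130 genes, all with the same sign, 61 higher and 69 lower, where 3.22 and 3.33 would be called in both if calls were independent. Adult and hippocampal effects had r = 0.312, total brain and hippocampal effects r = 0.344. Number 5 stands in both Dicer-deficient groups of the last pair, and whether 1 mouse gave both libraries is not stated.

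LPS given to control mice tested the acute inflammatory response of microglia in total brain (n = 4 LPS, 3 steady state). Lcn2 rose from 4.07 ± 4.00 to 366 ± 201, the acute phase gene Saa3 from 34.5 ± 11.8 to 2090 ± 1340, the chemokine Ccl5 from 59.2 ± 35.9 to 2970 ± 2390, and the metallothionein Mt2 from 20 ± 8.67 to 1350 ± 941. P2ry12, the purinergic receptor that marks homeostatic microglia, fell from 9910 ± 1330 to 2400 ± 2460, a call lost with DESeq2. Sall1, a transcription factor of microglial identity, fell from 1140 ± 138 to 397 ± 301. In all, 946 genes rose and 951 fell, 660 and 684 at least 2-fold.

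Further LPS increases in controls were S100a9 (6.34 ± 1.28), Lrg1 (5.52 ± 0.37), Ehd1 (4.84 ± 0.72) and Cd300lf (4.57 ± 0.63), with adjusted p of at most 0.00506. Ptgs2, the prostaglandin synthase, was listed at 0 at steady state and at 8.38 ± 2.21 after LPS. The fructose transporter gene Slc2a5 (-4.20 ± 0.58), the receptor gene Nrp1 (-3.84 ± 0.71) and Nav1 (-3.45 ± 0.63) fell. Cbfa2t3 (-4.32 ± 0.88), Npnt (-3.40 ± 0.72), Gpr34 (-3.32 ± 0.69) and Tln2 (-3.21 ± 0.71) fell as well, calls that DESeq2 did not make, nor edgeR with either scaling for Cbfa2t3 and Npnt.

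In control microglia LPS raised 22 of 29 cytokine and chemokine genes either way, Tnfsf9 by 3.51 ± 0.49 (list adjusted p = 6.88e-19; 0.343 estimated). Of 39 interferon genes 28 rose, 34 over the list alone, with Ifitm3 at 3.54 ± 0.56, Irf7 at 3.05 ± 0.50 and Isg15 at 2.36 ± 0.40 (adjusted p = 2.83e-21; 0.343 estimated). The Toll-like receptor and NF-kB list rose with 15 of 32 genes higher and 1 lower, 18 and 2 over the list alone, Tlr2 by 2.14 ± 0.39 (adjusted p = 1.19e-05; 0.343 estimated). Glycolysis rose with 8 of 22 higher and 2 lower, 11 and 3 over the list alone, Ldha by 1.68 ± 0.31 and Slc2a1 by 2.00 ± 0.38 (adjusted p = 0.000731; 0.343 estimated). Homeostatic genes fell, 13 of 30 and 16 over the list alone (adjusted p = 7.98e-07; 0.366 estimated), and adult-stage genes fell, 6 of 18 with 3 higher, or 8 and 3 over the list alone (adjusted p = 0.018; 0.551 estimated).

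Ribosomal protein genes rose in LPS controls, 8 of 46 and 10 over the list alone, Rpsa by 1.40 ± 0.28 (adjusted p = 0.000421; 0.513 estimated). Markers of monocytes and neutrophils rose, 9 of 20 with 2 lower, or 10 and 2 over the list alone, S100a8 by 5.33 ± 0.97, or 4.37 without library 33 (adjusted p = 7.04e-05; 0.343 estimated). Immediate early genes, 6 of 26 higher and 7 over the list alone, and oxidative phosphorylation, 0 of 34 either way, rose too (adjusted p = 0.0371 and 0.0287, and 0.702 and 0.551 estimated). Those calls were lost in 3 and 4 of 7 refits, with adjusted p = 0.413 without LPS 17 and 0.0915 without LPS 32. Cd74 (1.79 ± 0.29) and Cd40 (3.25 ± 0.64) rose in the antigen presentation list, which did not pass. Median, mean and test differed in sign for the perinatal, miR-155 and miR-146a, lysosome and oligodendrocyte lists, none of which passed.

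Control LPS library 33 stood apart from the other LPS controls, with Tnf at 76.3 against 437 to 590. Without it 3388 genes were called instead of 1897. The count was 877 and 883 without LPS 31 and 32, 918, 992 and 872 without steady-state 7, 8 and 9, and 1048 with only the groups compared. With edgeR 62% (TMM) and 61.6% (RLE) of the called genes were higher, against 49.9%.

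LPS in Dicer-deficient mice tested the same response without Dicer in total brain (n = 4 LPS, 3 steady state). Mt2 rose from 25.8 ± 21.5 to 5160 ± 850, Lcn2 from 16.6 ± 15.6 to 1890 ± 515, the cytokine Il1b from 17.4 ± 9.90 to 1300 ± 338, and Cxcr2, a chemokine receptor of neutrophils, from 1.83 ± 2.59 to 208 ± 71.1. P2ry12 fell from 7340 ± 797 to 1030 ± 228, a call lost with DESeq2, and Sall1 from 744 ± 89.3 to 205 ± 35. In all, 1631 genes rose and 1718 fell, 1125 and 1206 at least 2-fold.

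Saa3 (6.83 ± 0.83), Lrg1 (6.75 ± 0.37), the kinase Fgr (5.95 ± 0.52), osteopontin (Spp1, 5.91 ± 0.82) and Ehd1 (5.75 ± 0.72) rose, with adjusted p of at most 7.14e-05. Zdhhc14 (-4.30 ± 0.52), Kcnk12 (-4.18 ± 0.71), Garnl3 (-4.08 ± 0.64), Nbeal2 (-3.78 ± 0.52), Nrp1 (-3.78 ± 0.71), Plxna4 (-3.76 ± 0.63) and E2f1 (-2.52 ± 0.47) fell. Cytokines and chemokines rose, 26 of 29 and 27 over the list alone (adjusted p = 2.14e-20; 0.14 estimated). Interferon genes rose, 34 of 39 and 37 over the list alone, Irf7 by 3.36 ± 0.50 and Isg15 by 3.09 ± 0.40 (adjusted p = 2.05e-18; 0.375 estimated). The Toll-like receptor and NF-kB list rose with 25 of 32 higher and 4 lower, 26 and 4 over the list alone, with Nfkb2 at 2.82 ± 0.23, Tnfaip3 at 3.13 ± 0.29 and Nfkbiz at 3.90 ± 0.37 (adjusted p = 1.74e-15; 0.13 estimated). Antigen presentation rose with 10 of 24 higher and 2 lower, 11 and 3 over the list alone, Cd40 by 6.55 ± 0.64 and Cd74 by 2.97 ± 0.29 (adjusted p = 0.00333; 0.462 estimated).

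Homeostatic genes fell after LPS in Dicer-deficient microglia, 14 of 30 with 1 higher, 17 and 1 over the list alone (adjusted p = 4.03e-05; 0.421 estimated). Immediate early genes (10 of 26 higher, 1 lower) and glycolysis (8 of 22 higher, 2 lower) rose with adjusted p = 0.000227 and 0.00853, and adjusted p = 0.421 each estimated. When adjusted over the list alone, 13 and 11 were higher and 1 and 3 lower. Oxidative phosphorylation rose, 4 of 34 over all genes and 0 over the list alone (adjusted p = 0.0376; 0.462 estimated), a call lost in 4 of 7 refits with adjusted p = 0.104 without steady-state 12. Markers of monocytes and neutrophils rose, 13 of 20 with 1 lower either way, among them Ly6c2 (4.79 ± 0.67) and Plac8 (4.94 ± 0.70) (adjusted p = 2.47e-06; 0.14 estimated). Erythroid markers rose, 7 of 11 either way (adjusted p = 0.0032; 0.462 estimated), among them Hba-a1 (4.24 ± 0.88), whose reads can be shared with other globin copies. Median, mean and test differed in sign for the perinatal, miR-155 and miR-146a, border macrophage, neuron and astrocyte lists, none of which passed.

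After LPS the genotypes were compared directly in total brain (n = 4 each). Chst2 was at 283 ± 56.7 in Dicer-deficient and 7.55 ± 1.47 in control microglia, the integrin gene Itgb3 at 1250 ± 325 and 87.0 ± 14.5, and Il4i1, an amino acid oxidase, at 1220 ± 569 and 88.5 ± 46.5. Il1b rose from 250 ± 164 to 1300 ± 338 and its decoy receptor gene Il1r2 from 268 ± 176 to 1730 ± 438. Apoe fell from 1470 ± 303 to 231 ± 62.8 and Prkcb from 1060 ± 140 to 193 ± 38.7. In Dicer-deficient microglia 503 genes were higher and 687 lower, 335 and 495 at least 2-fold. With edgeR 51% (TMM) and 50.7% (RLE) of the called genes were higher, against 42.3%.

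Other genes higher without Dicer after LPS were Cxcr2 (4.33 ± 0.48), Kcnn4 (3.11 ± 0.32), Perp (3.20 ± 0.46), Lrg1 (2.94 ± 0.35), the cell cycle kinase Cdk6 (0.96 ± 0.16) and the repressor Bach1, a miR-155 target (1.45 ± 0.26). Nos2, the inducible nitric oxide synthase, rose from 1.40 ± 1.93 to 10.4 ± 2.45, a call DESeq2 did not make, and Lcn2 (2.48 ± 0.57) and Ly6c2 (2.86 ± 0.62) rose, calls lost with a pseudocount of 0.1. Slamf9 (-3.08 ± 0.50), Slco4a1 (-2.67 ± 0.25), Nrp1 (-2.87 ± 0.65), Fcrls (-1.59 ± 0.22), Cd79b (-3.07 ± 0.46) and the DNA damage kinase Atm (-1.47 ± 0.26) fell. Rps2 (-3.70 ± 0.67) and Rpl26 (-3.65 ± 0.63) were lower too, but their reads can be shared with near-identical gene copies, which leaves these values uncertain.

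The Toll-like receptor and NF-kB list was higher without Dicer after LPS, 12 of 32 genes and 20 over the list alone with 1 lower, with Icam1 at 1.5 ± 0.16, Nfkb2 at 1.85 ± 0.21 and Relb at 1.70 ± 0.25 (adjusted p = 2.24e-11; 0.166 estimated). Cytokines rose, 6 of 29, or 7 with 1 lower over the list alone (adjusted p = 0.00045; 0.556 estimated), a call lost without control 33 (adjusted p = 0.168). Antigen presentation rose, 5 of 24 with 2 lower, 8 and 2 over the list alone, Cd74 by 2.23 ± 0.27 and Cd40 by 3.09 ± 0.59 (adjusted p = 0.00249; 0.542 estimated), a call lost without control 17 (adjusted p = 0.0581). Ribosomal protein genes fell, 13 of 46 and 27 over the list alone, Rps15 by 0.80 ± 0.15 (adjusted p = 6.08e-09; 0.172 estimated). Markers of monocytes and neutrophils rose, 6 of 20 and 7 over the list alone (adjusted p = 8.18e-06; 0.166 estimated). Neuronal markers rose, 2 of 15 and 3 over the list alone (adjusted p = 0.00486; 0.166 estimated), Rbfox3 by 2.09 ± 0.52, a call lost without Dicer-deficient 35.

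Interferon genes did not pass in this comparison, with 2 of 39 higher, Gbp5 by 2.08 ± 0.37 (median -0.03, adjusted p = 0.284), nor did homeostatic genes with 1 of 30 higher and 2 lower (adjusted p = 0.984). Median, mean and test differed in sign for the interferon, p53, small-RNA, oxidative phosphorylation, immediate early and endothelial lists. The count of 1190 genes was 729 and 723 without Dicer-deficient LPS 36 and 37.

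**Figure D2:**
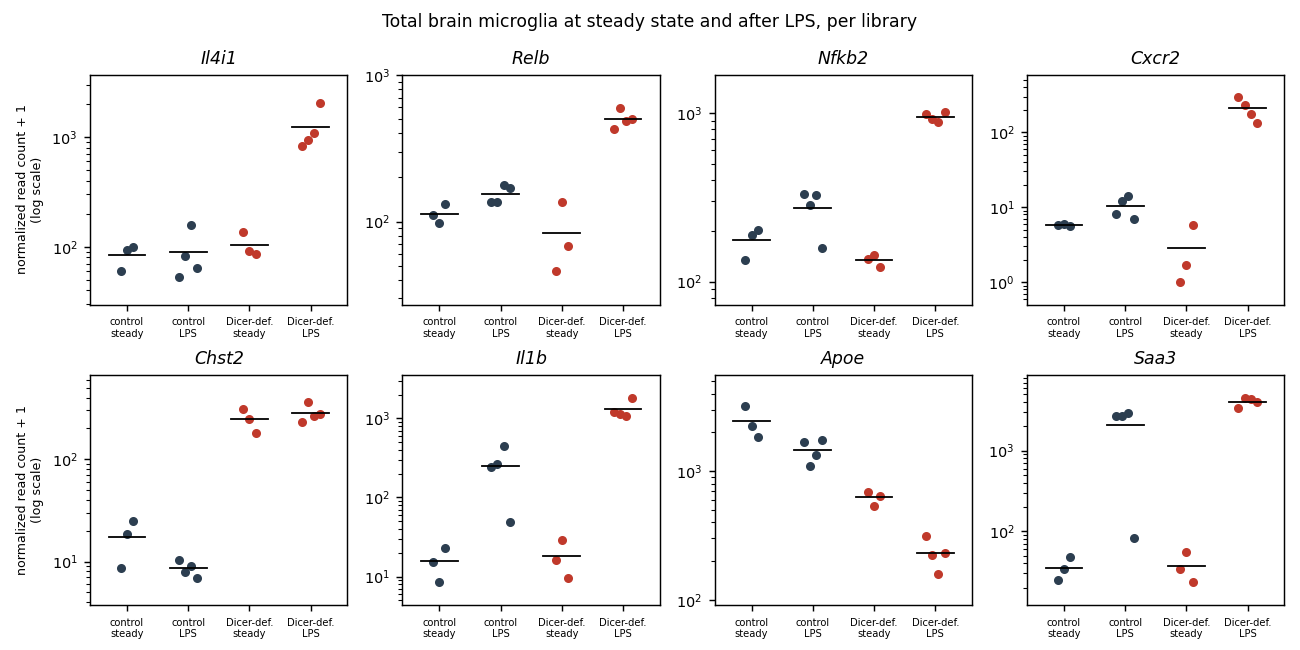
Normalized read count + 1 (log scale) of Il4i1, Relb, Nfkb2, Cxcr2, Chst2, Il1b, Apoe and Saa3 in the 4 total brain groups. Points are libraries and lines are group means; Il4i1, Relb, Nfkb2 and Cxcr2 lie highest in Dicer-deficient microglia after LPS.

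The interaction asked whether the LPS effect itself differed by genotype in total brain (14 libraries). The LPS effect was greater without Dicer for Cxcr2 (5.75 ± 0.73), Il4i1 (3.50 ± 0.49), the NF-kB subunits Relb (2.26 ± 0.38) and Nfkb2 (2.22 ± 0.32), Rbms1 (2.02 ± 0.28), the oxysterol receptor gene Gpr183 (1.80 ± 0.28) and Ninj1 (1.75 ± 0.26), and lower for the transporter gene Slco4a1 (-2.51 ± 0.38) and Camk1d (-1.63 ± 0.24). In all 17 genes were higher and 6 lower, with adjusted p of at most 0.0155 for those named here. Relb lost its call without control steady 9 or Dicer-deficient LPS 36, and the other genes named so far kept theirs in all 14 refits. Il1b (2.51 ± 0.78, adjusted p = 0.235), Cd40 (3.30 ± 0.90, adjusted p = 0.146) and Nos2 (2.57 ± 0.80, adjusted p = 0.239) did not pass.

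Of the lists, Toll-like receptor and NF-kB genes had a greater LPS effect without Dicer, 5 of 32 and 15 over the list alone (median 0.99, adjusted p = 1.34e-15; 0.115 estimated). Cytokines had 0 of 29 called either way, with a median of 0.89 (adjusted p = 7.33e-05; 0.664 estimated). Higher as well were immediate early genes (0 of 26 called, adjusted p = 0.0174), erythroid markers (0 of 11, adjusted p = 0.0363), antigen presentation (0 of 24, adjusted p = 0.0433) and monocytes and neutrophils (0 of 20, adjusted p = 0.0433), each with adjusted p = 0.664 estimated. Adjusted over the list alone, 1, 0, 2 and 2 were higher. These 4 calls were lost in 4, 5, 7 and 7 of 14 refits, with adjusted p = 0.184 without control steady 9, 0.346 without Dicer-deficient steady 11b, 0.338 without control LPS 17 and 0.17 without Dicer-deficient steady 5. Disagreement in sign between median, mean and test occurred for the small-RNA and oxidative phosphorylation lists.

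The interaction count of 23 was 14, 15, 36 and 92 without control LPS 17, 31, 32 and 33. It was 13 without control steady 9, 14 without Dicer-deficient LPS 36, LPS 37 or steady 5, and 37 without Dicer-deficient steady 11b. Only 3 genes were lower without control steady 7 or Dicer-deficient LPS 38. It was 52 with a pseudocount of 5 and 162 with DESeq2. Of the called genes 84.2% were higher with edgeR and RLE scaling, against 73.9%. Across 13423 genes, which are not independent replicates, the LPS effects of the 2 genotypes in total brain had r = 0.690, and 1356 of 1360 genes called in both had the same sign.

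In the hippocampus the LPS response of controls was measured in 2 against 2 libraries. Saa3 rose from 60.9 ± 58.9 to 4150 ± 367, Ccl5 from 129 ± 79.2 to 4490 ± 388, Il1rn, the interleukin 1 receptor antagonist, from 5.78 ± 1.53 to 840 ± 166, and Socs3, a suppressor of cytokine signaling, from 183 ± 11.8 to 2460 ± 477. Marco, a scavenger receptor gene, was listed at 0 at steady state and at 433 ± 161 after LPS. P2ry12 fell from 11000 ± 1210 to 960 ± 474, Gpr34 from 1820 ± 43.0 to 68.2 ± 57.0 and Slc2a5 from 714 ± 55.2 to 16 ± 15.4. Cd300lf (6.03 ± 0.53), Cd244 (6.09 ± 0.76), Mt2 (5.96 ± 0.68) and Cxcl10 (3.56 ± 0.52) rose, and Upk1b (-3.98 ± 0.39), H2-Eb1 (-3.93 ± 0.52), Tln2 (-3.93 ± 0.56) and Hpgd (-3.71 ± 0.29) fell, among 290 genes higher and 357 lower.

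Hippocampal homeostatic genes fell in LPS controls, 15 of 30 and 18 over the list alone (adjusted p = 6.78e-14), cytokines rose, 15 of 29 and 17 (adjusted p = 1.34e-15), and Toll-like receptor and NF-kB genes rose, 9 of 32, or 17 with 2 lower (adjusted p = 2.63e-09); with estimated correlation they kept adjusted p = 0.0086, 0.0322 and 0.0311. Interferon genes rose, 17 of 39 and 28 over the list alone (adjusted p = 1.35e-19; 0.0843 estimated). Immediate early genes rose, 8 of 26 and 9 (adjusted p = 1.17e-07; 0.0594 estimated), and adult-stage genes fell, 7 of 18 with 2 higher, or 10 and 3 (adjusted p = 0.00169; 0.0843 estimated). Glycolysis rose, 4 of 22 with 2 lower either way (adjusted p = 0.0133; 0.251 estimated), a call lost without LPS 16 (adjusted p = 0.0825). Erythroid markers rose, 0 of 7 over all genes and 5 over the list alone (adjusted p = 0.000655; 0.387 estimated), a call lost without LPS 15 (adjusted p = 0.0815). The count of 647 genes was 304 and 251 without LPS 15 and 16, 330 and 190 without steady-state 1 and 2, and 1120 with DESeq2. The signs of median, mean and test were mixed for the miR-155 and miR-146a, lysosome and oligodendrocyte lists.

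In Dicer-deficient hippocampus after LPS (n = 2 LPS, 3 steady state), Spp1 rose from 4.65 ± 4.06 to 2570 ± 1700, Il1b from 26.8 ± 8.80 to 1720 ± 315, the cytokine Tnf from 49 ± 18 to 1150 ± 192 and Socs3 from 633 ± 35.8 to 4540 ± 829. Apoe fell from 8920 ± 1320 to 142 ± 63.1, P2ry12 from 10500 ± 809 to 1200 ± 372, and the neutrophil granule gene Ngp from 1340 ± 316 to 1.37 ± 0.0302. S100a8 (-7.27 ± 1.30) and S100a9 (-8.91 ± 1.49) fell, calls lost without LPS 20. Pf4 was listed at 0 after LPS, against 91.9 ± 4.66. Sema6b (6.50 ± 0.61), Mt2 (6.31 ± 0.62), Sdc4 (5.47 ± 0.80) and Saa3 (5.39 ± 0.54) rose, and Cbfa2t3 (-6.50 ± 1.12), Slamf9 (-4.95 ± 0.62), H2-Aa (-4.51 ± 0.69) and Tmem140 (-4.41 ± 0.58) fell, among 478 genes higher and 570 lower.

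With estimated correlation 5 lists kept their calls in this comparison. Homeostatic genes fell, 14 of 30, or 14 with 1 higher over the list alone (adjusted p = 5.2e-09; 0.0166 estimated), cytokines rose, 20 of 29, or 23 with 1 lower (adjusted p = 6.63e-16 and 0.0295), Toll-like receptor and NF-kB genes rose, 18 of 32, or 21 with 2 lower (adjusted p = 8.35e-12 and 0.0166), immediate early genes rose, 9 of 26 and 12 (adjusted p = 1.43e-08 and 0.0451), and border macrophage markers fell, 6 of 17 and 7 (adjusted p = 0.000439 and 0.0479). Markers of monocytes and neutrophils fell, 6 of 19 and 9 over the list alone (adjusted p = 0.000217; 0.257 estimated). Interferon genes rose, 6 of 39 and 8 (adjusted p = 0.000439; 0.428 estimated), a call lost without LPS 20 (adjusted p = 0.219). Glycolysis rose, 5 of 22 with 1 lower, or 7 and 2 (adjusted p = 0.00225; 0.179 estimated), and mitosis fell with 1 of 32 lower, or 0 (adjusted p = 0.000844; 0.0814 estimated).

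Lysosomal (8 of 34 lower, 2 higher), ribosomal (3 of 46), perinatal (4 of 23, 3 higher) and oxidative phosphorylation genes (1 of 34) fell with adjusted p = 0.0166, 0.0269, 0.0449 and 0.0449, and 0.428, 0.285, 0.257 and 0.233 estimated. Adjusted over the list alone, 12, 3, 9 and 1 were lower and 4, 0, 5 and 0 higher. The first 3 calls were lost without LPS 18 (adjusted p = 0.0687, 0.0999 and 0.147) and the last without steady-state 4 (adjusted p = 0.156). The count of 1048 genes was 418 and 496 without LPS 18 and 20, and 1590 with DESeq2. Mixed signs of median, mean and test were seen in the adult-stage, antigen presentation and DNA replication lists.

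Compared after LPS in the hippocampus (n = 2 each), 20 genes were higher and 18 lower in Dicer-deficient microglia. Itgb3 rose from 67.7 ± 38 to 1260 ± 12.2 (4.32 ± 0.43). Apoe fell from 1960 ± 292 to 142 ± 63.1 (-3.85 ± 0.29) and Prkcb from 1040 ± 167 to 160 ± 8.54 (-2.68 ± 0.27). Rps2 (-4.84 ± 0.44) and Rpl26 (-4.35 ± 0.50) were lower, uncertain because of shared reads, and Rpl26 lost its call without control 16. Upk1b rose (3.48 ± 0.39). Chst2 rose (5.43 ± 0.69), a call lost without Dicer-deficient 18 or 20, and Il4i1 rose (3.38 ± 0.49), a call lost without any 1 of the 4 libraries. Lag3 (-2.75 ± 0.35) and Slamf9 (-5.07 ± 0.68) fell, calls lost without control 15, control 16 or Dicer-deficient 18, and Fcrls (-1.83 ± 0.25) fell, a call lost without control 16, Dicer-deficient 18 or Dicer-deficient 20. With only the groups compared, the calls of Rpl26, Upk1b, Chst2, Lag3, Slamf9 and Fcrls were lost. In total brain and hippocampus the effects after LPS had r = 0.484 across 12206 genes, which are not independent replicates, and all 34 genes called in both had the same sign.

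Ribosomal protein genes fell, 3 of 46 and 6 over the list alone (adjusted p = 1.17e-13; 0.0549 estimated). Interferon genes fell with 0 of 39 called either way and a median of -1.31 (adjusted p = 5.72e-09; 0.246 estimated), with Ifitm3 at -3.24 ± 0.86 (adjusted p = 0.189). Toll-like receptor and NF-kB genes rose with 0 of 32 called either way and a median of 0.56 (adjusted p = 4.86e-05; 0.113 estimated). Homeostatic genes rose, 1 of 30 with 1 lower, or 5 and 2 over the list alone (adjusted p = 0.00509; 0.113 estimated), and border macrophage markers fell, 0 of 17, or 2 over the list alone (adjusted p = 0.011; 0.155 estimated). Mitosis (0 of 32) and lysosomal genes (1 of 34, or 2 over the list alone) fell, and immediate early genes (0 of 26), adult-stage genes (0 of 18) and targets of miR-155 and miR-146a (0 of 28) rose. Their adjusted p was 0.0103, 0.0439, 0.0162, 0.0367 and 0.0367, and 0.165, 0.528, 0.261, 0.224 and 0.165 estimated. Mitosis, immediate early and adult-stage genes lost their calls without Dicer-deficient 18 (adjusted p = 0.107, 0.0576 and 0.412), and lysosomal genes and miR-155 and miR-146a targets without control 16 (adjusted p = 0.63 and 0.173). The count of 38 genes was 25, 12 and 8 without control 15, control 16 and Dicer-deficient 18, 40 (6 higher, 34 lower) without Dicer-deficient 20, 7 with only the groups compared and 218 with DESeq2. Median, mean and test had mixed signs in the antigen presentation, p53 and lymphocyte lists.

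The hippocampal interaction (9 libraries) called 0 genes higher and 2 lower, Apoe (-4.16 ± 0.39) and Rps2 (-4.77 ± 0.59). Of 12366 genes 706 had unadjusted p under 0.05, little above chance, and DESeq2 called 41. Apoe lost its call without control steady 1 or 2, and Rps2 without control LPS 15 or 16, control steady 1 or 2, Dicer-deficient LPS 18, or Dicer-deficient steady 5 or 6. Interferon genes had a lower LPS effect without Dicer (0 of 39 called, or 2 over the list alone, median -1.42, adjusted p = 2.47e-10; 0.253 estimated), as had ribosomal protein genes (1 of 46, or 2, adjusted p = 4.88e-07; 0.1 estimated). Homeostatic (0 of 30, or 1) and adult-stage genes (0 of 18 either way) had a higher one (adjusted p = 0.00276 and 0.000193, and adjusted p = 0.1 for both estimated). Lower as well were erythroid markers (0 of 7), monocytes and neutrophils (0 of 19), mitosis (0 of 32, or 1 over the list alone) and oxidative phosphorylation (0 of 34), with adjusted p = 0.000222, 0.014, 0.021 and 0.0248, and 0.387, 0.537, 0.253 and 0.253 estimated.

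The erythroid and monocyte and neutrophil calls of this interaction were lost without control LPS 15 (adjusted p = 0.0959 and 0.286), the mitosis and oxidative phosphorylation calls without control steady 1 (adjusted p = 0.192 and 0.212). The count of 2 was 4 without control LPS 16 or Dicer-deficient LPS 20, 0 without control steady 1 or 2, and 1 without Dicer-deficient LPS 18 or steady 5 or 6. Without control LPS 15, 1 gene was higher and 1 lower. Mixed in sign were the antigen presentation, DNA replication, p53, let-7, immediate early, neuron, astrocyte and endothelial lists. Il1b, at 2.71 ± 0.69, did not pass (adjusted p = 0.53).

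The developmental controls asked how microglia mature before and after birth. From E14 (n = 4) to P0 (n = 5) the immediate early genes Fos and Egr1 rose from 90.8 ± 75.1 to 2620 ± 1050 and from 120 ± 101 to 3910 ± 1620. Interferon-induced Ifi27l2a fell from 753 ± 128 to 59.4 ± 31.9, Irf7 from 201 ± 46.1 to 20.5 ± 11, and Cybb, a subunit of the phagocyte NADPH oxidase, from 416 ± 12.3 to 34.4 ± 14.2. Sall1 rose from 286 ± 6.21 to 455 ± 63.1. Of 13824 genes tested, 1146 rose and 1995 fell.

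Ttr, the transport protein made by choroid plexus, rose by 6.39 ± 0.45, Fosb by 5.69 ± 0.56, Dusp1 by 4.72 ± 0.43, Jun by 3.87 ± 0.36 and Junb by 3.26 ± 0.29. Hba-a1 (5.81 ± 0.63) and Hbb-bs (4.78 ± 0.76) were higher, globin genes with shared reads. The border macrophage scavenger receptor gene Cd163 rose by 3.57 ± 0.44. Igf2bp1, a let-7 target, fell by 4.55 ± 0.30, Oas2 by 4.17 ± 0.44, Ccnd2 by 3.30 ± 0.37, Rtp4 by 2.94 ± 0.38, Nes by 2.69 ± 0.23, Isg15 by 2.64 ± 0.27, the lactate transporter gene Slc16a3 by 2.07 ± 0.23 and Vim by 1.92 ± 0.18, as did Ifi204 (-3.08 ± 0.35) and Sox11 (-3.02 ± 0.36). Rpl34 was at -4.38 ± 0.92, uncertain because reads can be shared with Rpl34-ps1. Adjusted p was at most 0.00187 for these genes.

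Between E14 and P0, 33 of 39 interferon genes fell and 36 over the list alone (median -2.05, adjusted p = 2.6e-21; 0.0355 estimated), and adult-stage genes rose, 9 of 18 with 1 lower, or 11 and 2 (adjusted p = 1.63e-06; 0.0117 estimated). Immediate early genes rose, 21 of 26, or 22 with 1 lower (adjusted p = 2.09e-24 and 0.0626 estimated). Jun and Junb, which rose, stand in both this list and the adult-stage list. Cytokines rose, 11 of 27 with 5 lower, or 13 and 9, among them Ccl2 (2.87 ± 0.28), Ccl3 (2.71 ± 0.33) and Osm (3.00 ± 0.25) (adjusted p = 0.00261; 0.278 estimated). Glycolysis fell, 10 of 22 and 12 (adjusted p = 7.28e-05; 0.062 estimated). DNA replication and mitosis fell, 10 of 34 each and 10 and 11 over the list alone, with Dut at -1.61 ± 0.27 (adjusted p = 0.000183 and 0.000365, and 0.255 and 0.28 estimated).

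Homeostatic (7 of 30 higher, 2 lower), Toll-like receptor and NF-kB (13 of 32, 3 lower), lysosomal (5 of 36, 5 lower), erythroid (8 of 11, 1 lower), oligodendrocyte (5 of 11, 1 lower) and miR-155 and miR-146a target genes (6 of 28, 1 lower) rose from E14 to P0. Their adjusted p was 0.000949, 0.00011, 0.00457, 1.12e-06, 0.0107 and 0.0296, and 0.0975, 0.16, 0.239, 0.0975, 0.0823 and 0.0823 estimated. Over the list alone, 9, 13, 5, 8, 6 and 6 rose. Antigen presentation (13 of 23 lower, 1 higher), oxidative phosphorylation (8 of 34), neuronal (11 of 20), astrocyte (7 of 16) and endothelial genes (6 of 17) fell. Their adjusted p was 0.0043, 0.000689, 2.57e-05, 0.00261 and 0.0315, and 0.241, 0.256, 0.159, 0.0653 and 0.304 estimated, and 14, 10, 13, 9 and 7 were lower over the list alone. The miR-155 and miR-146a and the endothelial calls were lost without E14 library 2 (adjusted p = 0.0638 and 0.157). With edgeR and TMM 50.3% of called genes were higher, against 36.5%. No single sign held for the perinatal, p53, small-RNA, lymphocyte and sex-linked lists.

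From P0 to adult (n = 5 each) homeostatic Tmem119 rose from 1210 ± 250 to 8250 ± 1600 and Selplg, a selectin ligand, from 643 ± 244 to 14100 ± 2390. Genes of amoeboid postnatal microglia fell, Spp1 from 1000 ± 306 to 9.33 ± 3.99 and Igf1, a growth factor, from 223 ± 45.1 to 2.40 ± 2.15, as did the cell cycle gene Top2a, from 361 ± 83.2 to 11.1 ± 3.69, and Mrc1, the mannose receptor of border macrophages, from 458 ± 126 to 16.6 ± 8.03. In all, 2589 genes rose and 3244 fell. Cx3cr1 split the adults, at 490, 1190 and 940 in libraries 2, 4 and 5 and at 7450 and 8690 in 1 and 3.

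Klk8 (5.09 ± 0.54), Lrba (4.47 ± 0.22), Lrrc3 (4.28 ± 0.25), Endod1 (3.55 ± 0.22), Slc1a3 (3.45 ± 0.48), Col27a1 (3.43 ± 0.21) and Sult1a1 (3.36 ± 0.44) rose, as did the adhesion receptor gene Adgrg1 (2.48 ± 0.13) and Cd14 (2.05 ± 0.17). Gpx3 (-8.57 ± 0.28), the RNA-binding protein gene Igf2bp3 (-8.01 ± 0.23), Apoc1 (-6.48 ± 0.29), Cdk1 (-4.45 ± 0.20), the Fanconi anemia gene Fanca (-4.29 ± 0.35), Chek1 (-3.55 ± 0.32), Csf1 (-3.15 ± 0.20), the replication helicase gene Mcm6 (-3.10 ± 0.20) and Dab2 (-2.83 ± 0.21) fell, all with adjusted p of at most 6.14e-06. Lin28b, which blocks let-7 maturation, was listed at 0 in all adults and at 8.57 ± 4.18 at P0. Hspa1a was higher (4.87 ± 0.47), with reads that can be shared with Hspa1b.

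With estimated correlation 7 lists kept their calls from P0 to adult. Perinatal genes fell, 22 of 24 (adjusted p = 1.21e-16; 0.000227 estimated), mitosis, 33 of 34 (1.36e-30 and 0.00533), DNA replication, 32 of 34 (8.76e-22 and 0.00998) and border macrophage markers, 11 of 17 (1.1e-06 and 0.0278). Homeostatic genes rose, 21 of 30 (adjusted p = 5.33e-10; 0.00533 estimated), adult-stage genes, 14 of 18 with 1 lower (5.35e-09 and 0.00144), and antigen presentation, 19 of 23 (5.35e-09 and 0.0241), with H2-DMa at 2.38 ± 0.22 and H2-DMb1 at 2.01 ± 0.16. Adjusted over the list alone these counts were the same, except 34 for mitosis.

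DNA repair (26 of 36 lower, 1 higher), ribosomal protein (28 of 46), oxidative phosphorylation (27 of 34), neuronal (16 of 20), erythroid (8 of 11) and let-7 target genes (13 of 30, 4 higher) fell from P0 to adult. They had adjusted p = 2.92e-08, 4.26e-08, 2.93e-08, 1.1e-06, 2.61e-05 and 0.0473, and 0.0537, 0.153, 0.0707, 0.09, 0.142 and 0.0707 estimated. Adjusted over the list alone, 27, 30, 28, 17, 8 and 13 were lower. Rps19 fell by 2.28 ± 0.22 and Cox6c by 1.78 ± 0.21. Interferon (11 of 39 higher), miR-155 and miR-146a target (11 of 28, 3 lower) and Toll-like receptor and NF-kB genes (12 of 32, 7 lower) rose with adjusted p = 0.000407, 0.029 and 0.0473, and 0.283, 0.0542 and 0.444 estimated, and with the same counts over the list alone. The let-7 and Toll-like receptor calls were lost in 5 and 6 of 10 refits, with adjusted p = 0.0672 without adult 5 and 0.137 without P0 library 1. Different signs of median, mean and test were found for the small-RNA, glycolysis, lymphocyte and endothelial lists.

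**Figure D3:**
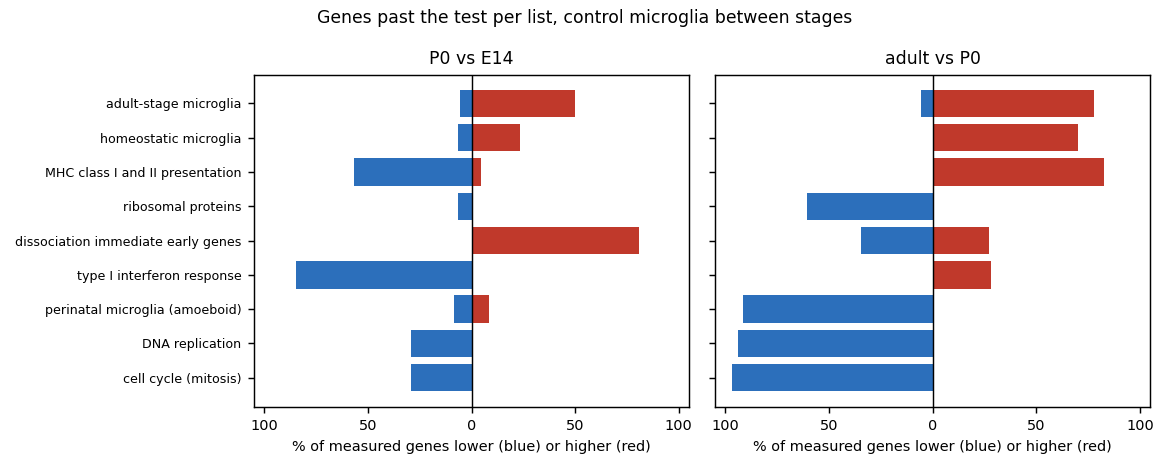
Percent of the measured genes of 9 lists that were called lower (blue, to the left) or higher (red, to the right) at P0 against E14 and in adult against P0 controls. Interferon genes were lower at P0 (33 of 39), whereas perinatal, DNA replication and mitosis genes were lower in adults (22 of 24, 32 of 34 and 33 of 34).

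Adults against E14 (n = 5 and 4) spanned both steps, with 2822 genes higher and 4264 lower. Adgrg1 rose from 152 ± 24.9 to 1270 ± 154, Col27a1 from 38.1 ± 11.9 to 1230 ± 72.8, Jun from 177 ± 50.1 to 4890 ± 1670 and Numb from 102 ± 11 to 505 ± 44.3. Gpx3 fell from 847 ± 198 to 1.07 ± 0.744, Igf2bp3 from 407 ± 40.2 to 0.287 ± 0.642, the mitotic gene Ube2c from 430 ± 19.3 to 5.64 ± 4.10 and Birc5 from 343 ± 42.8 to 5.51 ± 4.45, while Igf2bp1 and Sox11 were listed at 0 in all adults. Ttr (7.56 ± 0.45) and Sult1a1 (5.92 ± 0.47) rose.

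All 18 adult-stage genes rose between E14 and adult, 25 of 30 homeostatic genes rose with 1 lower, and 13 of 28 miR-155 and miR-146a targets rose with 2 lower (adjusted p = 3e-14, 6.03e-12 and 0.00124, and 0.000246, 0.00303 and 0.0119 estimated). All 34 mitosis genes, 33 of 34 DNA replication genes and 22 of 24 perinatal genes fell (adjusted p = 2.27e-25, 9.93e-20 and 7e-12, and 0.0109, 0.0119 and 0.000682 estimated). Adjusted over the list alone the counts of these 6 lists were the same, except 26 for homeostatic genes. Interferon genes fell, 25 of 39 with 1 higher either way, with Oas2 at -3.54 ± 0.44 (adjusted p = 0.000193; 0.223 estimated). Of 34 oxidative phosphorylation genes 32 fell, or 33 over the list alone (adjusted p = 5.7e-10; 0.0612 estimated). Toll-like receptor and NF-kB (14 of 32, 1 lower), antigen presentation (9 of 23), immediate early (19 of 26, 2 lower) and oligodendrocyte genes (6 of 11, 2 lower) rose, with adjusted p = 2.37e-05, 0.00302, 9.96e-11 and 0.0259, and 0.102, 0.161, 0.132 and 0.085 estimated. DNA repair (27 of 36, 1 higher), glycolysis (12 of 22, 4 higher), ribosomal protein (34 of 46), border macrophage (12 of 17, 1 higher), neuronal (19 of 20) and astrocyte genes (9 of 16, 2 higher) fell, with adjusted p = 6.16e-08, 0.026, 7.44e-08, 0.000795, 1.7e-08 and 0.0112, and 0.0612, 0.156, 0.143, 0.0885, 0.0612 and 0.0778 estimated. Over the list alone these counts were the same, except 8 for antigen presentation, 20 for immediate early, 35 for ribosomal protein, 13 for border macrophage and 10 for astrocyte genes. With edgeR and TMM 50.9% of the called genes were higher, against 39.8%. Among lists that did not pass, signs were mixed for small RNA, lysosome and lymphocytes, and sex-linked genes had 0 of 5 called (adjusted p = 0.694).

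The newborn comparison asked how loss of Dicer from early development alters microglia at birth (n = 2 Dicer-deficient, 3 control). Of 5 P0 controls it used 1 to 3, as the labels assign. The lectin gene Fcna rose from 85.8 ± 3.35 to 1410 ± 449, Ddit4, a stress-induced inhibitor of mTOR signaling, from 22.8 ± 3.22 to 589 ± 252, and Cdkn1a, the p53-induced cell cycle inhibitor p21, from 471 ± 133 to 1330 ± 69.8. Prkcb fell from 435 ± 8.41 to 82.1 ± 27.9, Ecscr from 295 ± 23.2 to 50.3 ± 4.99 and the replication helicase gene Mcm2 from 132 ± 15.2 to 27.0 ± 1.48. Of 13064 genes tested, 136 rose and 58 fell.

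Other newborn increases were Adgre5 (4.77 ± 0.47), Pik3ip1 (4.73 ± 0.38), Unc119 (4.26 ± 0.35), Perp (3.99 ± 0.50), Acp5 (3.62 ± 0.44), H2-T23 of MHC class I (2.66 ± 0.32), Vim (2.66 ± 0.30), the galectin gene Lgals3 (2.54 ± 0.38), Cebpb (2.00 ± 0.34), Socs3 (1.88 ± 0.36), Ccl2 (1.87 ± 0.34) and Fcgr2b (1.38 ± 0.28). Slc2a5 (-3.93 ± 0.43), the nuclease gene Exo1 (-3.59 ± 0.67), Fscn1 (-3.12 ± 0.40), Tspan7 (-2.37 ± 0.37), Cwc22 (-2.31 ± 0.29), Mcm4 (-2.21 ± 0.39), Lpl (-1.75 ± 0.32) and Mcm6 (-1.49 ± 0.28) fell. Rpl34 (4.89 ± 0.50) and Rpl26 (-1.69 ± 0.30) share reads with near-identical copies and are uncertain. The largest adjusted p of these genes was 0.0439. Of the newborn genes named here, 0 were called without control 2, and only Fcna, Ddit4, Pik3ip1 and Unc119 were called without control 1. The number of called genes was 4, 0 and 40 without control 1, 2 and 3, and 683 and 4716 without Dicer-deficient 1 and 2. Other tools were not run without control 2. Without control 3 the calls of Mcm2, Lgals3, Tspan7, Cwc22 and Rpl26 were lost, and those of Cdkn1a, Cebpb, Socs3, Ccl2, Fcgr2b, Exo1, Mcm4, Lpl and Mcm6 both then and with a pseudocount of 0.1. The count was 108 with a pseudocount of 0.1, 593 with the replicate block, 367 and 390 with edgeR (TMM, RLE) and 553 with DESeq2.

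DNA replication genes fell in newborn Dicer-deficient microglia, 4 of 34 and 20 over the list alone (median -1.10, adjusted p = 2.31e-10; 0.119 estimated), as did DNA repair genes, 1 of 36 and 2 over the list alone (adjusted p = 9.45e-06; 0.197 estimated), and mitosis genes, 0 of 34 and 3 (adjusted p = 0.00308; 0.613 estimated). The p53 list rose, 3 of 26, or 4 over the list alone (adjusted p = 0.00522; 0.391 estimated). Antigen presentation rose, 1 of 22, or 10 with 1 lower over the list alone (adjusted p = 9.45e-06; 0.391 estimated). Interferon genes rose with 0 of 38 called, or 10 with 1 lower over the list alone (adjusted p = 0.000117; 0.354 estimated), with Irf7 at 1.80 ± 0.38 (adjusted p = 0.0513).

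Immediate early genes (3 of 25, or 7 with 2 lower over the list alone) and lysosomal genes (1 of 36 either way) rose in newborns, with adjusted p = 0.00522 and 0.00995, and 0.724 and 0.354 estimated. Erythroid (0 of 11, or 5 over the list alone) and neuronal markers (0 of 19 either way) fell, with adjusted p = 0.00522 and 0.0479, and 0.354 and 0.673 estimated. Mitosis, p53 and interferon calls were lost without Dicer-deficient 2 (adjusted p = 0.24, 0.0906 and 0.0915), immediate early and neuronal calls without control 1 (adjusted p = 0.266 and 0.357). Dicer-deficient 1 held 992317 reads and had Cx3cr1 at 647. The ribosomal RNA precursor Rn45s made up 1.39 and 0.786% of reads in the Dicer-deficient newborns and 0.316 to 0.494% in the 3 controls, and 11595 and 12685 genes had a read, against 12833 to 13710. The signs of median, mean and test differed for the homeostatic, adult-stage, cytokine and sex-linked lists. Across 10464 genes, which are not independent replicates, newborn and adult Dicer effects had r = 0.142, and 26 of 32 genes called in both had the same sign.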

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

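The tests of library 33 in total brain were chosen after the result was seen, and their genes changed after a first run. The test of single libraries flags about 5% of groups by chance, and here 19 of 325 (5.85%) had a library far from the others, 6 of 70 (8.57%) of them among the LPS controls of total brain.

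In those LPS controls, library 33 stood far from the other 3 for Cd300lf (107 against 1090 to 1520), Ehd1 (27.7 against 353 to 484), Mt2 (53.5 against 1340 to 2230), Npnt (251 against 11.2 to 13.4), Saa3 (82.2 against 2660 to 2940) and Sall1 (848 against 223 to 274). Of the genes called higher after LPS in Dicer-deficient microglia, 49.5% lay above all 3 steady-state controls in library 33, against 78.3 to 84.5% in the other LPS controls and 25% for a library like the controls. Of those called lower, 47.7% lay below all 3, and S100a8 was at 679 against 0 to 3.4 in them and 30.1 to 85.6 in the other LPS controls. For these genes the values argue against a mislabelled steady-state control, but the treatment has no other measure. Over 832 genes the library lay a median 29.7% of the way from the steady-state mean to the mean of the other LPS controls (quartiles 10.4 to 51.6), a value consistent with a smaller LPS response in that animal.

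Other libraries far from their group were adult control 2 for Hsf2bp (136), 3 for Dusp2 (96.7) and 4 for Cd79b (190), and E14 library 4 for Cdca3 (319). At P0 they were library 1 for Lin28b (1.45), 3 for Dut (25.8) and 4 for Ifi204 (72.6) and Rpl34 (657). In developmental adults they were library 1 for Igf2bp3 (1.44) and 5 for Adgrg1 (1000), and among Dicer-deficient LPS libraries 35 for Tmem37 (495), 36 for Rpl26 (243) and 38 for Cdk6 (971).

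A difference in LPS effect between genotypes, by the test of the interaction, was called for 23 genes in total brain and for 2 in the hippocampus. In total brain the named ones were Cxcr2 (5.75), Il4i1 (3.50), Relb (2.26), Nfkb2 (2.22), Rbms1 (2.02), Gpr183 (1.80), Ninj1 (1.75), Itgb3 (1.69), Nfkbie (1.63) and Tnip1 (1.43), and with a negative sign Slco4a1 (-2.51), Fkbp4 (-1.75), Samd1 (-1.70), Camk1d (-1.63), Tmem37 (-1.60) and Tbc1d5 (-1.49). Of 14 refits without 1 library, 11 ended the call of Itgb3, 10 those of Fkbp4 and Tbc1d5, 9 of Samd1, 8 of Tmem37, 7 of Nfkbie, 3 of Tnip1 and 2 of Relb. Fkbp4 lost it with edgeR (TMM and RLE), and Samd1 and Tmem37 with RLE. In the hippocampus they were Apoe (-4.16) and Rps2 (-4.77). Of 100 genotype splits only the real one gave 23 genes (highest other 4). They mix the genotype effect too and cannot isolate the interaction.

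For 6 other counts only the real split gave as many, a share of 0.01 to 0.0286, unadjusted. The real and highest other counts were 569 and 1 in adults, 3349 and 852 for LPS in Dicer-deficient total brain, and 1190 and 14 for the genotypes after LPS. They were 3141 and 1134 for P0 against E14, 5833 and 17 for adult against P0, and 7086 and 5016 for adult against E14. For LPS in control total brain 2 of 35 splits gave as many as 1897, so the splits alone cannot exclude chance. In other libraries, of hippocampal controls, 495 of these genes were called after LPS too, 494 with the same sign. The other split gave 3472 genes and moves library 33 to the steady-state side, which points to a structure of the samples. For the genotypes at steady state in total brain (292, highest other 1), 10 splits are too few for a share under 0.05.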

How the results depend on the processing

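Chosen after seeing the data were edgeR, DESeq2, sex as a covariate and the correlations without library 33. No called fold change of a named gene reversed in sign under the alternatives run, and the cause of the changes below was not tested. The side with more called genes did change under some settings, in total brain for both LPS comparisons and both genotype comparisons (107 higher and 185 lower at steady state against 303 and 242 with DESeq2), in the hippocampus for LPS in controls and the genotypes after LPS, for P0 and adults against E14, and in newborns. Counts of called genes stayed within 1.5 times under the settings run, except as follows. In adults sex as a covariate gave 354. In total brain only the groups compared gave 1048 for LPS in controls, DESeq2 gave 545 for the genotypes at steady state, and a pseudocount of 5 and DESeq2 gave 52 and 162 for the interaction. In the hippocampus DESeq2 gave 1120 and 1590 for LPS in controls and Dicer-deficient mice, 231 for the genotypes at steady state, 218 after LPS and 41 for the interaction. Hippocampal genotypes at steady state gave 8 and 42 with pseudocounts of 0.1 and 5, 43 with only the groups compared, 33 with TMM and 35 with RLE, and those after LPS 7 with only the groups compared. Newborns gave 108 with a pseudocount of 0.1, 593 with the replicate block, 367 with TMM, 390 with RLE and 553 with DESeq2. The replicate block gave 450 in adults, 3348 for P0 against E14, 5869 for adult against P0 and 7013 for adult against E14. The numbers did not pair the libraries, with correlations of same-number pairs of -0.012 to 0.04 (adult) and -0.233 to 0.249 (development), and of different-number pairs of -0.081 to 0.057 and -0.274 to 0.258.

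Leaving out 1 library gave 344 to 634 genes in adults and, in total brain, 872 to 3388 and 2351 to 3466 for LPS in controls and Dicer-deficient mice, 89 to 216 and 723 to 1187 for the genotypes at steady state and after LPS, and 13 to 92 for the interaction. In the hippocampus the ranges in the same order were 190 to 330, 418 to 854, 4 to 12, 8 to 40 and 0 to 4. They were 2141 to 2815 for P0 against E14, 5290 to 5584 for adult against P0, 6373 to 6987 for adult against E14 and 0 to 4716 for newborns. Where 1 library remained in a group, it was assumed to vary like those of the other groups.

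With an estimated correlation the number of called lists was 0 of 4 in adults, 0 of 10 for each LPS effect in total brain, 0 of 5, 6 and 6 for the genotypes and the interaction there, 3 of 8, 5 of 13, 0 of 3, 0 of 10 and 0 of 8 in the hippocampus in the same order, 2 of 18, 7 of 16 and 6 of 18 in development, and 0 of 10 in newborns. Most calls, 122, were lost, and most of the 298 unchanged list results were not calls. Correlations across genes, by Spearman and then by Pearson for genes of higher expression, were 0.411 and 0.608 between adult and total brain, 0.293 and 0.471 between adult and hippocampus, and 0.299 and 0.41 between total brain and hippocampus. For LPS they were 0.632 and 0.831 between genotypes in total brain, and 0.591 and 0.83 between tissues in controls. Higher expression gave 0.819 between tissues in Dicer-deficient mice and 0.722 between genotypes in the hippocampus. Over all genes Pearson r between genotypes in total brain was 0.69, and 0.714 without library 33. Of the gene values refitted, DESeq2 ended 16 calls and made 6, RLE 10 and 3, TMM 8 and 3, no filter 8 and 1, only the groups compared 18 and 2, a pseudocount of 0.1 25 and 0, of 5 1 and 5, the replicate block 2 and 2, and sex 8 and 0. Leaving out 1 library ended 293, made 4 and left 2523. In simulated data limma missed most genes changed 2-fold.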

Other observations

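The tests of genes that varied widely within a group and of dividing cells were chosen after the results were seen. So were the genes named in this part. Some genes moved the same way in several sets of Dicer-deficient microglia that share no library, although number 5 stands in both total brain and hippocampus and is not said to be 2 mice. Of 10239 genes tested in adults, steady-state total brain, steady-state hippocampus and newborns, 18 were called in the same direction in at least 3 sets, 13 higher and 5 lower, where 0.061 would be if calls were independent. Called in all 4 were Ifi30 (2.39, 2.49, 2.37 and 2.23 in that order) and Ecscr, a cell surface regulator of chemotaxis (-1.09, -1.43, -1.74 and -2.53). The others higher were Cd34, Csf2ra, Ctsl, Hist1h2bc, Igsf8, Nid2, Perp, Scarb1, Tgfbi, Tmem37, Ube2g2 and Zdhhc12, and the others lower Amotl1, Bmp1, Prkcb and Sox4. Csf2ra, the receptor chain for GM-CSF, was at 1.26, 1.35, 1.1 and 1.56. Sox4, a transcription factor gene, was at -1.47, -2.30, -1.77 and -1.71. For both the third was not called. Matching was by symbol, and Siglec5 (adults) and Siglecf may be the same gene. Refits without 1 library, run for only some of these genes, ended calls in the hippocampus and in newborns, and those of Ctsl and Sox4 in total brain.

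Genes beside Dicer1 on its chromosome gave no cluster of calls. Of its 50 nearest tested neighbours, 0 were called in adults, in total brain and hippocampus at steady state, in hippocampus after LPS or in newborns, where 5.15, 2.18, 0.17, 0.307 and 1.48% of all genes were called. In total brain after LPS 3 were (6%, against 8.87% of all genes), Otub2, Serpina3f and Serpina3h, and the Serpina3 genes can share reads.

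Histone genes formed a further group in adult Dicer-deficient microglia. Of 38 measured, 18 rose and 0 fell, with a median of 1.67 (log2), against medians of 0.26 in total brain and 1.1 in hippocampus at steady state and -0.21 in newborns, differences that were not tested. Reads split between near-identical genes are argued against as the whole cause, since the summed values of all 5 histone classes were higher in all 3 Dicer-deficient libraries than in all 4 controls, H2B with 3350 against 684 and H1 with 2580 against 846. Read depth is argued against too, since 16 of the 18 stayed called with every library thinned to 898451 reads. More dividing cells stay open, since the DNA replication list had a median of 0.10 but mitosis genes one of 0.84 that did not pass.

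A few genes were on in some libraries and off in others of the same group, 13 genes in 45 occurrences, among them Spint1, Ccr6, Klk8, Slc2a5, Ttr and Rpl34. RNA of another cell type is argued against as the common cause, since the median correlation of these genes within groups was -0.002 over 97 pairs on different chromosomes. Strain variants that segregate among the mice may be a source, since all 13 genes were on and off within control groups too. They cannot be told apart from other causes, since the only 2 pairs of neighbouring genes, both Hspa1a with Hspa1b, share reads.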
